A study of Mus musculus with 23 samples.

How the data were processed

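The samples were 23 RNA-seq libraries from mouse olfactory epithelium, made from RNA that was pulled down with an antibody against phosphorylated ribosomal protein S6 (pS6). S6 on the ribosomes of a neuron is phosphorylated after the neuron has been active, so this pull-down enriches RNA of activated cells. Per the labels, C57BL/6 mice at postnatal day 21 were exposed for 1 h to an odor, acetophenone or TMT (trimethylthiazoline, a compound from fox secretions), each at 1% or 100%, or to a control. The acetophenone experiment held 11 libraries of 5 litters, with controls of litters 1 to 5, the 100% dose in litters 1 to 3 and the 1% dose in litters 3 to 5. The TMT experiment held 12 libraries, with control, 1% and 100% in each of litters 1 to 4. Per the labels' protocols, the libraries were made from amplified cDNA with a transposon-based kit.

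Per the submitters' processing notes, the authors used Bowtie, bedtools and the mm10 genome build. The versions and the gene annotation are not given in the sources used here. Each deposited file lists 23481 gene symbols with 20 value columns and no header. The values rise or stay level from column to column (0 decreases in all files), and they were read as running sums over reads that align to 1 place, then up to 2 places, and so on to 20. The deposited column used for every comparison is the first, whose values are whole-number raw counts and were read as counts of uniquely aligned reads. The deposited last column, whose values need not be whole, was read as estimated counts that also take in reads with several alignments, shared out between their places. These estimated counts were rounded to whole numbers and used only as an alternative chosen after the data had been seen. The 18 columns between them were not used. This reading of the columns comes from the values and not from a header.

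Unique counts summed to between 2118099 and 9526932 per library, which was 51.2 to 71.9% of the estimated counts. Leaving out reads with several alignments lowers genes that have near-identical copies: the count of Rps6, which has processed pseudogenes, was at most 16 in the first column and at least 5006 in the last. Genes whose counts were the same in every library or nearly so (Hba-a1 and Hba-a2, Hbb-bs and Hbb-b1, Hbb-bt and Hbb-b2, Ugt2a1 and Ugt2a2, Olfr207, Olfr208 and Olfr209, Olfr250 and Olfr899, Olfr257 and Olfr285) share reads or exons, so each such group is 1 measurement. The lists were tested with all members and, as an alternative, with 1 member per group whose counts differ by under 5% of their sum. A share of counts on odorant receptors in a single library has a 95% Wilson interval. The limit that a count of 0 allows was taken as 3 counts. Intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules.

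Libraries were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10, estimateDisp, glmQLFit and the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Each acetophenone dose was fitted with the controls of its own litters, and the TMT doses in 1 fit of all 12 libraries. The filter took in a gene with enough counts in any libraries of a fit, as many as the smallest group held. A receptor near its limit could therefore enter through odor libraries alone. Shares of receptors and tests of the receptor list rest on sets chosen in that way. The comparison of the acetophenone doses used all 11 libraries with litter as a block, since the doses share only litter 3. Responses to the 2 odors were compared as a difference of differences, each odor against its own controls. The comparisons, tests, gene lists, the replicate block and the other settings to be tried were fixed before the data were examined.

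The labels give each library a litter, so the litter numbers pair libraries across groups. The code series in the library titles changes between litters (litter 1 against litters 2 to 4 for TMT, and litter 1, litters 2 and 3, and litters 4 and 5 for acetophenone), so a batch of libraries and a litter cannot be told apart. In deviations from the group means, libraries of the same litter correlated across genes at 0.57 to 0.80 for 100% acetophenone, 0.72 to 0.89 for 1% acetophenone, 0.04 to 0.29 for 100% TMT, 0.02 to 0.34 for 1% TMT and -0.04 to 0.36 between the TMT doses. Another litter correlated more than the own one in 3 TMT cases: litters 3 (0.13 against 0.02) and 4 (0.06 against 0.02) at 1%, and litter 4 between the doses (0.27 against -0.04). Genes are not independent replicates, and these values only describe the pairing. The fit with litter as a replicate block is printed beside the fit without the block because it changed the calls, and values said to be within litters come from it. Both fits were tested on simulated counts with 200 changed genes. These counts were drawn from the litter means and dispersions that the fit with the block gave. The comparison therefore favours that fit by construction and does not show which fit suits the real libraries better. For 100% acetophenone (11564 genes) the fit without the block recovered 0% of genes changed by 1.5 and 0% of those changed by 3 on the log2 scale, and the fit with the block recovered 71% and 89%, with 20 false calls among 180. For 1% acetophenone (12077 genes) the shares were 0% and 0% without the block and 70% and 94% with it, with 15 false calls among 179. For 100% TMT (13233 genes) they were 15% and 61% without the block and 30% and 70% with it, with 5 false calls among 105. For the difference between the odors at 100% (13033 genes) they were 0% and 3% without the block and 9% and 47% with it, with 7 false calls among 63.

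The genes named are, for each comparison with control and among genes past the threshold, the 10 receptors higher, the 5 receptors lower, the 5 other genes higher and the 5 other genes lower with the smallest p, or the 2 with the smallest p where none of a kind passed. For the dose and odor contrasts they are the 5 genes per direction with the smallest p among those past the threshold. Omp, S100a5, Fos, Egr1 and the known acetophenone receptors Olfr151 (M71) and Olfr160 (M72) were named throughout. The rule was applied to the fit without the block as planned and, after the data had been seen, to the fit within litters. Few genes are described in full and the rest are summarised.

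The gene lists were odorant receptors (symbols that begin with Olfr, 1102 in the files after 20 pseudogene symbols were left out), trace amine-associated receptors, immediate early genes, activity-dependent genes of olfactory neurons, olfactory transduction genes, markers of mature and of immature olfactory neurons, of globose basal and dividing cells, horizontal basal cells, sustentacular cells, Bowman gland and secretory cells, microvillar cells and ionocytes, respiratory ciliated cells, immune cells, red blood cells, ensheathing glia and endothelium, and vomeronasal neurons, genes of the heat shock and unfolded protein response, ribosomal proteins, xenobiotic and oxidative stress genes, and sex-linked genes. Each was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and against no change with fry, which asks whether the genes of a list move on balance 1 way. All were adjusted over the lists of a comparison. Lists with under 2 tested members gave no test.

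Other settings fixed in advance were the replicate block, DESeq2 1.42.0 with its size factors, RLE scaling, robust hyperparameters, no filter on low counts, a stricter filter with a minimum count of 50, other sets of controls, leaving out each replicate in turn, receptors adjusted over the list alone, and calls at an adjusted p of 0.1. Chosen after the data had been seen were the estimated counts, the replicate block combined with the other settings, the block without each litter in turn, scaling to receptor counts alone, receptor shares without each litter, lists with 1 member per group of genes that share counts, and a correction for GC content and transcript length in which a smooth trend (lowess, span 0.3) of each library's log counts on both properties was removed. The correction was also tested on simulated counts. With a simulated trend of -0.1 log2 per percent of GC content, false calls for 100% TMT (13233 genes) went from 1199 to 6, and 38% and 69% of genes changed by 1.5 and by 3 on the log2 scale were recovered. For 100% acetophenone (11564 genes) false calls went from 2199 to 22, and 64% and 93% were recovered. The simulated trend was stronger than the real one. Its Spearman correlation in unchanged genes was -0.67 for TMT and -0.82 for acetophenone, against -0.45 and -0.18 across real genes. The false calls without correction therefore do not estimate those in the real libraries. The correction also removes any true change that follows GC content or length.

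Positions, GC content and sequence likeness come from GENCODE M21, which is on GRCm38, the same assembly as mm10. Of the 23481 symbols, 21871 matched 1 annotated gene, and 94.3% of the genes tested had a GC content and length. The receptor share of counts was compared with exact permutation tests, 2-sided. Likeness of receptors was the share of 30-base words of transcripts, or of words of 3 amino acids of the longest open reading frame (at least 250 amino acids), that a pair has in common. Plots and tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.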

Results

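RNA bound to ribosomes with phosphorylated S6 was sequenced from the olfactory epithelium of mice exposed to acetophenone, to TMT or to a control, in order to find the odorant receptor genes carried by neurons that an odor had activated. An olfactory neuron expresses 1 receptor gene, so RNA of a receptor that is enriched in the pull-down after exposure points to the neurons that carry it. In the acetophenone experiment there were 5 control libraries, 3 at 1% and 3 at 100%, and in the TMT experiment 4 each of control, 1% and 100%. Unique counts per library ranged from 2389806 to 4151769 in acetophenone controls, 2118099 to 3998370 at 1% acetophenone and 2187268 to 2946194 at 100%. In the TMT experiment they ranged from 4069851 to 7609265 in controls, 2869995 to 9526932 at 1% and 2672161 to 8347796 at 100%.

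Odorant receptors took a small share of all counts, and that share was larger with odor than in the control of the same litter in most pairs. With 100% acetophenone the share was 0.605% ± 0.293 (SD, n = 3) against 0.387% ± 0.169 in controls of the same litters, higher in 3 of 3 litters by 1.41 to 1.69 times. An exact permutation test gave p = 0.3, where 3 libraries against 3 allow no p under 0.1. With 100% TMT the share was 0.115% ± 0.0772 (SD, n = 4) against 0.0532% ± 0.0456, higher in 4 of 4 litters by 1.38 to 5.28 times (exact permutation p = 0.171, smallest possible 0.0286). At 1% the shares were 0.402% ± 0.279 (SD, n = 3) for acetophenone against 0.289% ± 0.179 in its controls, higher in 2 of 3 litters (exact permutation p = 0.6). For 1% TMT the share was 0.106% ± 0.108 (SD, n = 4) against 0.0532% ± 0.0456, higher in 4 of 4 litters (exact permutation p = 0.457). Exact sign-flip tests within litters, which were at their floor for 100% acetophenone and both TMT doses, gave p = 0.25 for 100% acetophenone, 0.5 for 1% acetophenone and 0.125 for each TMT dose, and with so few litters a sign-flip test cannot pass. Without each litter in turn, in both groups, the ratio of means stayed between 1.47 and 1.61 for 100% acetophenone (1.56 with all), 1.26 and 1.59 for 1% acetophenone (1.39), 1.61 and 2.93 for 100% TMT (2.17) and 1.73 and 2.15 for 1% TMT (2). The control of TMT litter 1 weighs most: without it alone the TMT ratios were 3.77 at 100% and 3.48 at 1%, and without the control of litter 3 the 1% acetophenone ratio was 2.11. When only the 1% acetophenone library of litter 3 was left out and its control kept, the ratio went from 1.39 to 0.834, and likewise from 2 to 0.994 without the 1% TMT library of litter 1, since litters differ in level. TMT libraries of litters 2 to 4 held few receptor reads, with 167 to 275 receptors detected in all but the 100% library of litter 4, which had 526.

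**Figure D1:**
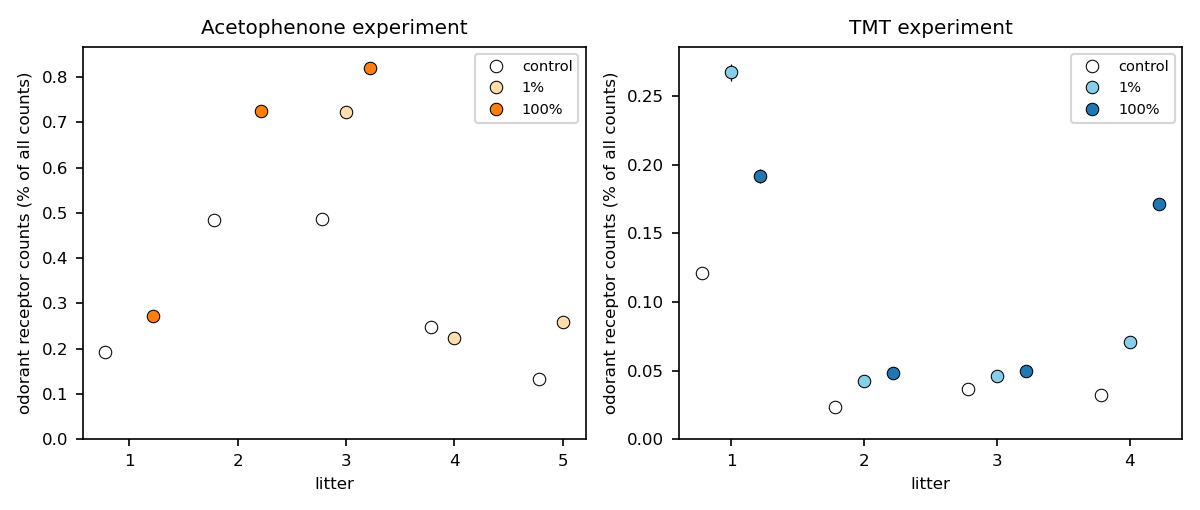
Share of unique counts on odorant receptor genes (% of all counts) in each library, by litter, for the acetophenone experiment (left) and the TMT experiment (right). Each point is 1 library, with a 95% Wilson interval that is mostly smaller than the symbol; the 100% library lay above the control of its litter in all 3 acetophenone litters and all 4 TMT litters.

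With 100% acetophenone, 10 odorant receptor genes rose within litters, each in 3 of 3 litters, and none fell. Olfr745 (chromosome 14, 50639388 to 50643885) had the smallest p and rose 9.13-fold, from 25.18 ± 17.97 to 234.2 ± 148.7 CPM (counts scaled to the library size that TMM gives; SD, n = 3), a log2 fold change of 3.19 (SE 0.24, edgeR adjusted p = 0.002 with litter as a block). Olfr30 (chromosome 11, 58454105 to 58462270) rose 5.84-fold, from 13.11 ± 4.629 to 78.4 ± 34.96 CPM (log2 2.55, SE 0.26, edgeR adjusted p = 0.00817). Olfr923 (chromosome 9, 38826545 to 38830300) rose 9.43-fold, from 7.976 ± 3.774 to 84.44 ± 52.04 (log2 3.24, SE 0.43, edgeR adjusted p = 0.0311). Olfr376 (chromosome 11, 73371246 to 73377836) rose from 5.486 ± 4.723 to 42.1 ± 27.56 CPM (log2 3.05, SE 0.37, edgeR adjusted p = 0.0167). Olfr937 (chromosome 9, 39058851 to 39064951) went from 1, 3 and 2 counts in the control libraries to 25, 122 and 71 (log2 5.08, SE 0.52, edgeR adjusted p = 0.00817). Olfr19 (log2 4.29), Olfr1047 (4.23), Olfr1026 (2.81), Olfr1104 (2.76) and Olfr136 (2.18) made up the rest, with edgeR adjusted p from 0.00898 to 0.0342. The 1 other gene that passed was Pcdh10, an adhesion protein of the protocadherin family whose level in olfactory neurons depends on their activity, which rose 4.3-fold from 36.04 ± 17.15 to 157 ± 77.82 CPM (chromosome 3, 45378398 to 45435623; log2 2.11, SE 0.20, edgeR adjusted p = 0.00679).

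Without the litter block, edgeR called 0 of the 11564 genes tested with 100% acetophenone, with 48 higher and 13 lower at an unadjusted p under 0.05, and 30 of the 48 were receptors. DESeq2 without the block called 5, all receptors. Adjusted over the list alone, the block gave 36 of the 321 receptors tested higher and 0 lower. Of those 321, 104 were higher in every litter (32.4%) and 27 lower (8.41%), where chance gives 12.5% each; of the other genes, 14.4% were higher and 13.5% lower in every litter. Without litter 1, 2 or 3 the fit within litters called 28, 7 and 3 genes, of which 19, 2 and 1 were receptors. Fold changes within litters fell with the GC content of the transcript (Spearman -0.18 across genes, which are not independent). Receptors are GC-poor (median 39.1%), and after each library was corrected for GC content and length the block called 7 genes: Olfr745, Olfr30, Olfr937, Olfr923, Olfr19, Olfr1104 and Pcdh10. Olfr376, Olfr1047, Olfr1026 and Olfr136 no longer passed. Over all other settings tried their log2 fold changes stayed at or above 2.74, 3.51, 2.38 and 1.6.

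**Figure D2:**
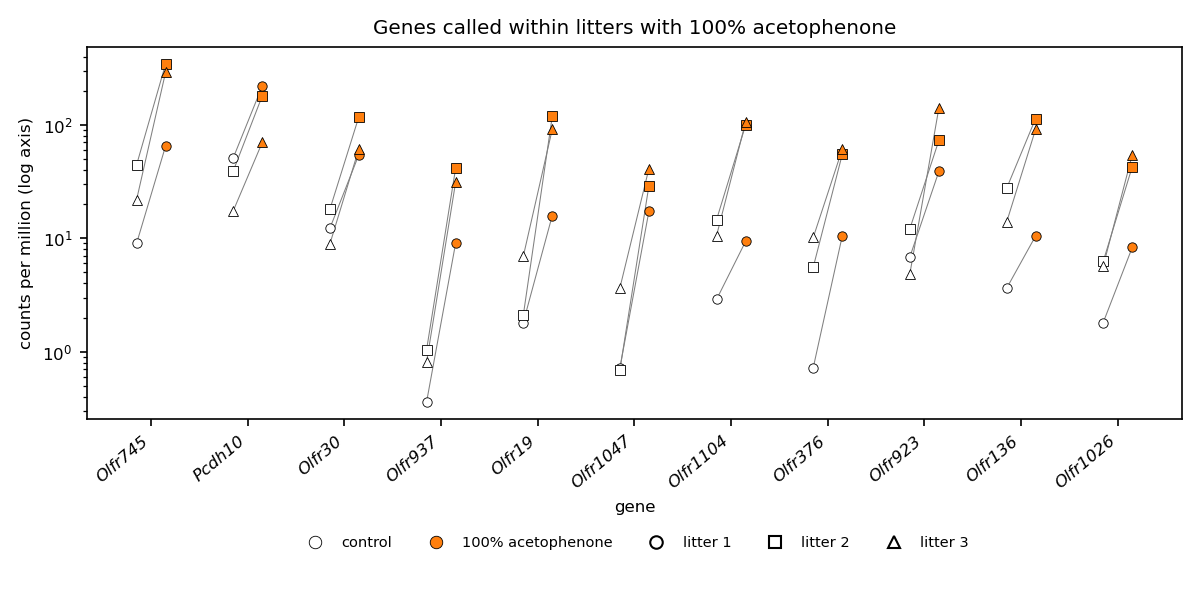
CPM (scaled counts, log axis) of the 11 genes past the threshold within litters with 100% acetophenone. Each symbol is 1 library, white for control and orange for 100% acetophenone, its shape gives the litter, and grey lines join the libraries of a litter. Each of the 11 genes was higher in 3 of 3 litters.

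Of the genes that report neuronal activity, Pcdh10 rose with 100% acetophenone and Fos and Egr1 were higher without passing over all genes. Fos had a log2 fold change within litters of 2.12 (SE 0.52, edgeR adjusted p = 0.551) and Egr1 of 1.84 (SE 0.46, edgeR adjusted p = 0.585), each higher in 3 of 3 litters, and both passed when adjusted over the list alone (0.0231 for each). S100a5, a calcium-binding protein of active olfactory neurons, was level (log2 0.00), and Omp, the marker of mature olfactory neurons, had a log2 fold change of 0.39; neither passed. The lower genes with the smallest p (Mical1 -1.42, Ifi27l2a -1.06, Tspan15 -1.16 and Col5a3 -1.87) did not pass, nor did Rffl (1.49) or the receptors Olfr1323 (-2.96) and Olfr63 (-2.76).

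Among 19 gene lists tested with 100% acetophenone, camera with its preset correlation put odorant receptors higher than other genes (median log2 fold change 0.38, 230 of 321 positive, adjusted p = 4.77e-16). Immediate early genes (median 0.22, adjusted p = 0.0167), activity-dependent genes of olfactory neurons (median 0.28, adjusted p = 0.00975) and vomeronasal neuron markers (5 of 5 positive, adjusted p = 0.0326) were also higher. Ribosomal proteins (median -0.19, adjusted p = 0.00757), markers of ensheathing glia and endothelium (median -0.33, adjusted p = 0.039) and immune cell markers (median -0.21, adjusted p = 0.0459) were lower. With an estimated correlation none of these passed (adjusted p = 0.37 for receptors and 0.342 for the other 6 lists). The other 12 lists had adjusted p from 0.058 to 0.691. Within litters, camera with its preset correlation also put mature neuron markers (adjusted p = 0.00741) and transduction genes (adjusted p = 0.0347) higher, and glia and endothelium no longer passed (adjusted p = 0.0784). With an estimated correlation the smallest adjusted p within litters was 0.302. The median log2 fold change of receptors within litters was 0.41, and 0.15 after the GC and length correction.

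With 1% acetophenone, 1 gene rose within litters: Olfr923, the receptor on chromosome 9 that also rose at 100%. It went from 3.98 ± 2.4 to 86.18 ± 64.56 CPM (SD, n = 3), a 19.4-fold rise in 3 of 3 litters (log2 4.28, SE 0.34, edgeR adjusted p = 0.0203 with litter as a block). Adjusted over the list alone, 4 of 234 receptors were higher within litters (Olfr923, Olfr491, Olfr1377 and Olfr983) and 1 was lower (Olfr140, log2 -0.74). Olfr983 over all genes (log2 2.39, adjusted p = 0.291), Olfr376 (1.15, adjusted p = 0.434) and Olfr30 (0.63, adjusted p = 0.638) did not pass in edgeR. The same holds for Calm4 (5.45), Rock1 (1.23), Myh9, the heavy chain of non-muscle myosin (-1.63), 2610015P09Rik (-1.15) and Aebp1 (-1.09), for Cul4b (1.82), Cx3cl1 (2.08) and Myh10 (-1.28), which led the fit without the block, and for the receptors Olfr5 (-1.02) and Olfr1348 (-0.74). Fos had a log2 fold change of 0.89, Egr1 of 0.57 and S100a5 of 0.98, with edgeR adjusted p from 0.43 to 0.736.

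Without the block edgeR called 0 of 12077 genes with 1% acetophenone, with 50 higher and 43 lower at an unadjusted p under 0.05, 6 of the higher being receptors, and DESeq2 called 1, a receptor. Receptors were higher in every litter for 63 of 234 (26.9%) and lower for 16 (6.84%). Of the other genes, 16.5% were higher and 15% lower, where chance gives 12.5% each. Fold changes fell with GC content at this dose too (Spearman -0.34 across 11388 genes, which are not independent). The GC and length correction shifted receptor log2 fold changes by a median of -0.31, and Olfr923 still passed. Without litter 3 the fit within litters called 0 genes and without litter 5 it called 19, of which 2 were receptors; with estimated counts it called 0. Camera with its preset correlation put odorant receptors (median 0.36, 161 of 234 positive, adjusted p = 5.98e-09) and Bowman gland and secretory cell markers (median 0.38, 12 of 15 positive, adjusted p = 0.0206) higher, with adjusted p = 0.88 and 0.646 when the correlation was estimated. The other 17 lists had adjusted p from 0.0754 to 0.85; within litters xenobiotic and oxidative stress genes also passed with the preset correlation (adjusted p = 0.00703) and not with the estimated one (adjusted p = 0.926).

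EdgeR called no gene between 100% and 1% acetophenone. With litter in the model, it called 0 of 12873 genes, with 453 higher and 354 lower at an unadjusted p under 0.05, and DESeq2 called 5 higher and 9 lower. Without a filter edgeR called 3, without the 1% library of litter 5 it called 5, and without the 100% library of litter 1 it called 1. The genes with the smallest p were Dlk1 (log2 -5.56, SE 0.70, adjusted p = 0.0998), Olfr30 (1.80, SE 0.31, adjusted p = 0.68), Calm4 (-5.54), Pcdh10 (1.60, SE 0.32, adjusted p = 0.68), Olfr1449 (3.49), Atp2a1 (-3.59) and Slpi (-2.36). Dlk1 had 544 counts in the control of litter 1 and at most 20 in each other library. Fos (1.49), Egr1 (1.06), S100a5 (-0.80) and Omp (0.25) did not pass. The doses shared only litter 3, so the contrast rests mostly on each dose against its own controls.

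With 100% TMT, 9 odorant receptors rose and 1 fell within litters, and 235 other genes rose and 69 fell (314 in all, or 306 when genes that share their counts are taken as 1). Olfr1395 (chromosome 11, 49142274 to 49150453) rose 6.17-fold, from 4.352 ± 2.279 to 25.68 ± 8.99 CPM (SD, n = 4), in 4 of 4 litters (log2 2.63, SE 0.31, edgeR adjusted p = 0.00603 with litter as a block). Olfr30 rose from 7.859 ± 4.143 to 38.72 ± 18.06 (log2 2.33, SE 0.33, edgeR adjusted p = 0.0121), and Olfr376 went from 6, 1, 2 and 0 counts in the controls to 59, 87, 11 and 128 (log2 5.04, SE 0.75, edgeR adjusted p = 0.0143). Olfr96 (log2 5.45, SE 0.93, edgeR adjusted p = 0.0213), Olfr31 (4.94), Olfr350 (4.88), Olfr449 (4.34), Olfr131 (3.69) and Olfr531 (2.65) also rose, each in 4 of 4 litters, the last 5 with edgeR adjusted p from 0.0325 to 0.0482. Olfr222 (chromosome 11, 59570255 to 59576235) fell in 4 of 4 litters, from 43.46 ± 10.92 to 11.08 ± 5.997 CPM (log2 -2.01, SE 0.37, edgeR adjusted p = 0.0267). Adjusted over the list alone, 13 of 133 receptors were higher and 1 was lower, and with libraries scaled to their receptor counts 4 of the 13 still passed (median log2 fold change of the 13 from 4.34 to 3.28), with 3 lower. The controls of litters 2 to 4 held few reads of Olfr31, Olfr350, Olfr96 and Olfr376 (0 to 5 counts each), so these folds are imprecise. Olfr1413 (log2 -5.60, adjusted p = 0.143) did not pass in edgeR.

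**Figure D3:**
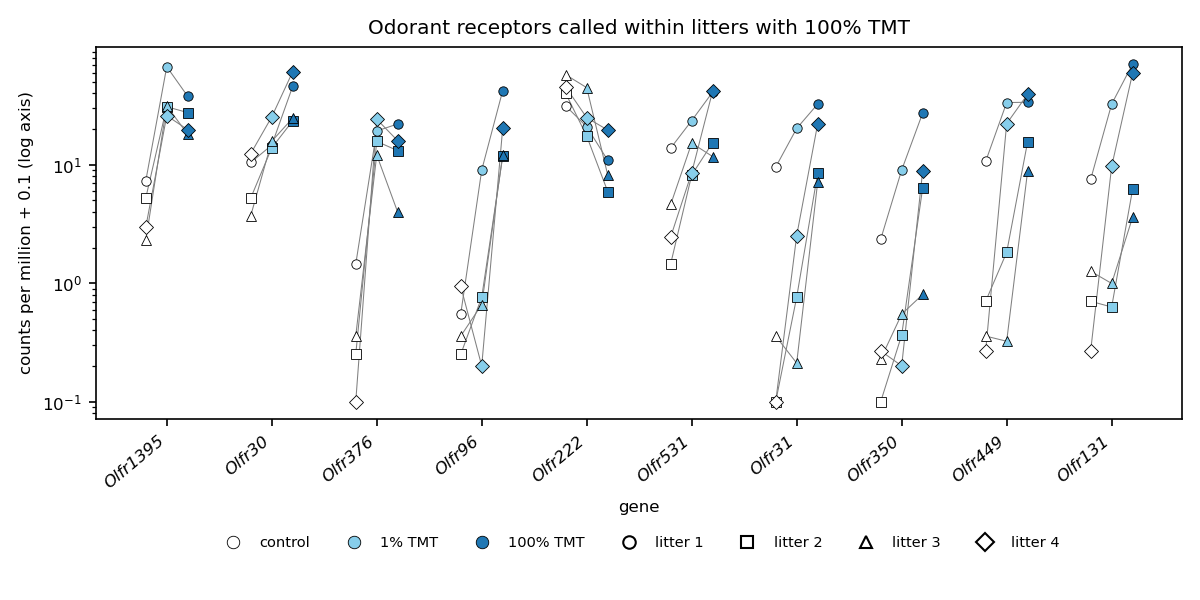
CPM plus 0.1 (log axis) of the 10 odorant receptors past the threshold within litters with 100% TMT. Symbols are single libraries of control (white), 1% (light blue) and 100% (dark blue), their shape gives the litter, and grey lines join a litter. From control to 100%, 9 receptors were higher and Olfr222 was lower in 4 of 4 litters.

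Among other genes with 100% TMT, the largest evidence was for Nfil3, a transcriptional repressor of the leucine zipper class, which rose 2.74-fold from 128.3 ± 43.53 to 364.3 ± 174 CPM (log2 1.45, SE 0.14, edgeR adjusted p = 0.00497). Asns, asparagine synthetase (1.97), Aldh1a1, a retinaldehyde dehydrogenase (2.82), Lrrc3b (1.88) and Zc3h14, an RNA-binding protein (2.06), rose with an edgeR adjusted p of 0.00603 each. Tubb3, the tubulin of neurons, fell from 491.2 ± 50.28 to 229.9 ± 36.11 CPM (log2 -1.10, SE 0.13, edgeR adjusted p = 0.00603). Myl9, a myosin light chain (-1.02), Crabp1, which binds retinoic acid (-0.96), Ddah2 (-0.87) and Tubb5, another tubulin (-0.78), fell with edgeR adjusted p from 0.012 to 0.0196. BC048546 (1.82), Zfp869 (4.91) and Col16a1 (-1.25), which led the fit without the block, passed within litters too. Higher genes were GC-poor and lower genes GC-rich: the median GC content was 45.1% for genes other than receptors that rose, 57.4% for those that fell and 50.8% for those tested, and fold changes fell with GC content (Spearman -0.45 across 12476 genes). After each library was corrected for GC content and transcript length, 45 genes were higher and 26 lower, and 49 of the 304 genes other than receptors still passed, among them Nfil3 (log2 1.59), Asns (1.67), Aldh1a1 (2.37), Lrrc3b (1.86), Zc3h14 (1.44), BC048546, Tubb3 (-0.81) and Tubb5 (-0.81). Myl9 (-1.02, SE 0.14, before and -0.64, SE 0.15, after), Crabp1 (-0.96 and -0.52), Ddah2 (-0.87 and -0.46) and Col16a1 (-1.25 and -0.89) no longer passed, nor did Zfp869, whose fold was nearly as large (4.91, SE 0.93, before and 4.39, SE 0.90, after, edgeR adjusted p = 0.0534). Of the receptors, Olfr1395, Olfr30, Olfr376, Olfr96 and Olfr222 still passed.

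**Figure D4:**
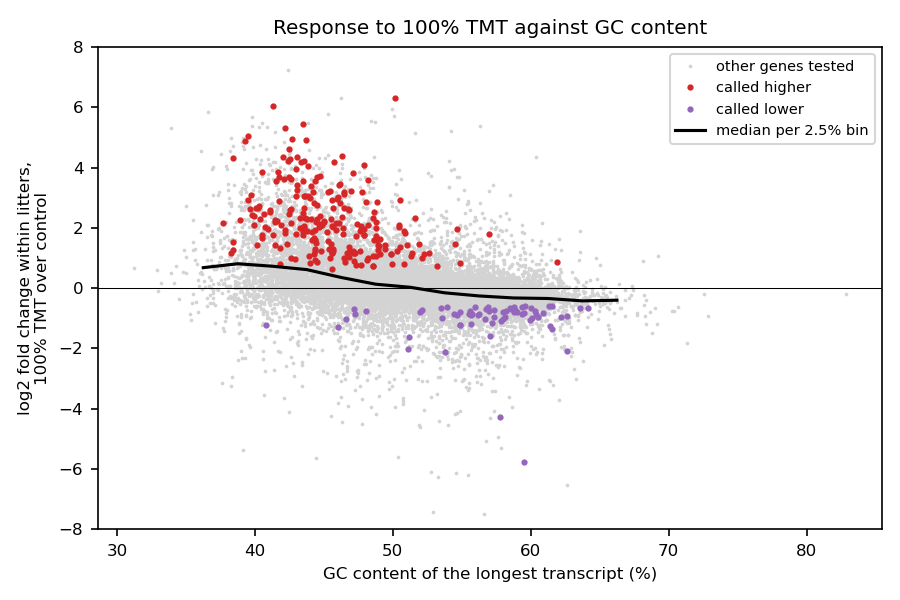
Log2 fold change within litters with 100% TMT against the GC content of each gene's longest transcript (%), for 12476 genes tested, with genes called higher in red, genes called lower in purple and the median per bin of 2.5% as a line. The median lies above 0 at low and below 0 at high GC content, and 3 genes lie outside the plotted range.

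Without the block edgeR called 0 of 13233 genes with 100% TMT (smallest adjusted p 0.0964), with 1102 higher and 842 lower at an unadjusted p under 0.05, and DESeq2 called 320 higher and 189 lower, of which 11 and 1 were receptors. Adjusted over the list alone without the block, 5 receptors were higher and 1 lower. Of the 133 receptors, 33 were higher in every litter (24.8%) and 5 lower (3.76%). Of the other genes, 14.6% were higher and 13.7% lower, where chance gives 6.25% each. Receptors near the limit of the filter could enter through odor libraries in which they were high. The 133 are therefore not a set chosen apart from the rise, and with only the 8 libraries compared 86 receptors were tested. Without litter 1, 2, 3 or 4 the fit within litters called 179, 1, 0 and 17 genes, of which 3, 0, 0 and 2 were receptors, and with only the 8 libraries compared it called 29, of which 2 were receptors.

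By gene list, immature olfactory neuron markers were lower with 100% TMT and several other groups were higher. Of 14 immature markers 13 were lower (median log2 -0.60, camera preset adjusted p = 4.1e-07; adjusted p = 0.334 with an estimated correlation), and within litters Tubb3, Marcksl1 (-0.75) and Lhx2 (-0.65) fell over all genes and 10 of 14 when adjusted over the list alone. After the GC and length correction 1 fell, and 5 over the list alone, while the weighted mean log2 fold change of the 14 went from -0.7 to -0.53. Of the immediate early genes (camera preset adjusted p = 0.027, estimated adjusted p = 0.667), Nr4a1 (log2 1.78), Nr4a2 (1.96) and Dusp1 (0.83) rose over all genes, and after the correction Nr4a2 (1.68) no longer passed. Egr1 (1.29, edgeR adjusted p = 0.0553) and Fos (1.44, edgeR adjusted p = 0.0885) passed when adjusted over the list alone. Sustentacular cell markers (median 0.64, camera preset adjusted p = 0.0176, estimated adjusted p = 0.334) included Ugt2a1 (2.40) and Ugt2a2 (2.41), glucuronosyltransferases with shared exons, which rose over all genes and no longer passed after the GC and length correction (1.55 and 1.56). Bowman gland and secretory cell markers (median 0.54, camera preset adjusted p = 0.0176, estimated adjusted p = 0.334) included Reg3g (3.80), an antimicrobial lectin, as the 1 member past the threshold over all genes, before and after the correction (3.69). Odorant receptors were higher as a list (median 0.88, 98 of 133 positive, camera preset adjusted p = 0.000407, estimated adjusted p = 0.667). Receptors near the limit of the filter could enter this list through odor libraries in which they were high. Within litters the list median was 1.39 before the GC and length correction, with receptors that share counts taken as 1, and 0.68 after it with all 133. The correction shifted receptor log2 fold changes by a median of -0.62. Red blood cell markers (median -0.54) and ribosomal proteins (median -0.23) were lower, each with a camera preset adjusted p of 0.0454 and estimated adjusted p of 0.667 and 0.689. With genes that share their counts taken as 1 neither passed without the block, with adjusted p = 0.197 for the 5 red blood cell markers left and 0.0532 for ribosomal proteins. Within litters ribosomal proteins then passed with the preset correlation in camera (adjusted p = 0.024) and not with the estimated one (0.607), and red blood cell markers did not pass (preset 0.0839). The other 13 lists had adjusted p from 0.0715 to 0.996, and within litters transduction genes passed with the preset correlation (adjusted p = 0.0417) and not with the estimated one (adjusted p = 0.549). By fry, which tests a list against no change and not against other genes, immature neuron markers passed without the block (adjusted p = 0.0412), and immature neuron markers (0.0133), receptors (0.0493) and sustentacular markers (0.0493) within litters. Omp (log2 0.13) and S100a5 (1.99, SE 0.80) did not pass. S100a5 was at 1049 and 367.7 CPM in the 100% libraries of litters 1 and 4, at 1071 in the 1% library of litter 1 and between 14.97 and 70.79 in the other 9 TMT libraries.

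With 1% TMT, 1 gene rose within litters: Olfr1395, which also rose at 100%. It went from 4.352 ± 2.279 to 38.75 ± 19.06 CPM (SD, n = 4), a 9.09-fold rise in 4 of 4 litters (log2 3.19, SE 0.31, edgeR adjusted p = 0.00524 with litter as a block). Olfr376 was at 17.74 ± 5.174 CPM against 0.44 ± 0.616 in controls (log2 5.61, SE 0.76, edgeR adjusted p = 0.0712) and passed when adjusted over the list alone, as 1 of 2 receptors. Olfr30 (log2 1.27, adjusted p = 0.577) and Olfr222 (-0.74, adjusted p = 0.712) did not pass in edgeR, nor did Malat1, a nuclear non-coding RNA (2.03, adjusted p = 0.269), Sptan1 (0.75), Mtmr2 (2.80), Zfp869 (4.06), Amdhd2 (-0.85), Amelx (-6.17), Notch2 (-5.45) and the receptors Olfr455 (-3.12) and Olfr524 (-3.55). Fos (0.24), Egr1 (0.33), Omp (0.20) and S100a5 (1.14) did not pass either.

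Without the block edgeR called 0 of 13233 genes with 1% TMT, with 389 higher and 179 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher, of which 2 were receptors. Receptors were higher in every litter for 16 of 133 (12%) and lower for 1 (0.752%), against 8.88% and 7.95% of the other genes, where chance gives 6.25% each. Without any 1 of the 4 litters the fit within litters called 0 genes, and with only the 8 libraries compared it called 0. Fold changes fell with GC content at 1% TMT too (Spearman -0.36 across 12476 genes, which are not independent). The GC and length correction shifted receptor log2 fold changes by a median of -0.35, and Olfr1395 still passed. Camera with its preset correlation put odorant receptors (median 0.58, adjusted p = 0.00276), mature neuron markers (median 0.33, adjusted p = 0.0346) and red blood cell markers (median 0.82, adjusted p = 0.00714) higher and immature neuron markers lower (median -0.22, adjusted p = 0.00933). With an estimated correlation the adjusted p was 0.969 for receptors and 0.773 for the other 3 lists. The 8 red blood cell markers are 5 measurements, with which the preset adjusted p was 0.0282. The other 16 lists had adjusted p from 0.052 to 0.991, and within litters transduction genes passed with the preset correlation (adjusted p = 0.0184) and not with the estimated one (adjusted p = 0.54).

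EdgeR called no gene between 100% and 1% TMT, 0 of 13233 without and with the block, with 294 higher and 403 lower at an unadjusted p under 0.05 without it. DESeq2 called 10 higher and 15 lower without the block and 219 with it, and within litters edgeR called 6 without a filter and 1 each with a stricter filter and robust hyperparameters. Within litters the smallest p belonged to Nfil3 (log2 1.12, SE 0.14, adjusted p = 0.0646), Lcn3, a lipocalin (1.67, SE 0.23, adjusted p = 0.0874), Obp2b, an odorant-binding protein (1.33, SE 0.26, adjusted p = 0.308), Zbtb25 (-1.26) and Col16a1 (-1.15), each in the same direction in 4 of 4 litters. Fos (1.20), Egr1 (0.96), S100a5 (0.85) and Omp (-0.08) did not pass.

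The response to 100% acetophenone was compared with the response to 100% TMT directly. Within litters, 9 genes of 13033 were lower in the acetophenone response than in the TMT response and 0 were higher by edgeR, with 376 higher and 1072 lower at an unadjusted p under 0.05. They were Olfr96 (log2 -6.36, SE 0.75, edgeR adjusted p = 0.0426), Psme4, a proteasome activator (-2.58, edgeR adjusted p = 0.0426), Crot (-2.96), Kcnj15 (-2.92), Grsf1 (-2.13), Hspa9 (-2.14), Phf14 (-2.22), Hspa4l (-2.79) and Aldh1a1 (-2.92). All 9 had their lowest mean in TMT controls: Psme4 stood at 14.39 ± 6.572 CPM in TMT controls (SD, n = 4) and 114.1 ± 56.62 with 100% TMT, against 233.5 ± 128.6 in acetophenone controls (n = 3) and 302.5 ± 156 with 100% acetophenone. P2rx3 (8.94), Pcdhga4 (7.39), Tubb3 (1.29), Ckb (1.21) and Zfp869 (-4.24) did not pass. Without the block edgeR called 0, with 75 higher and 554 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 9 lower. Over the other settings tried, the log2 fold changes ran from -6.84 to -5.73 for Olfr96, -2.69 to -2.06 for Psme4 and -2.22 to -1.86 for Grsf1. The difference between the responses rose with GC content (Spearman 0.38 across 12291 genes, which are not independent). The 9 calls were lost with RLE scaling (smallest edgeR adjusted p 0.0542), after the GC and length correction, and without acetophenone litter 1, 2 or 3 or TMT litter 4 (0 genes each), while without TMT litter 1, 2 or 3 there were 77, 20 and 26. At 1%, edgeR called 0 of 13720 genes with and without the block, with 48 higher and 109 lower at an unadjusted p under 0.05 without it, and DESeq2 called 1 lower. Olfr1395 (log2 -3.09, SE 0.48, adjusted p = 0.386) and Sptbn1 (-1.86, SE 0.29, adjusted p = 0.386) had the smallest p within litters, and Olfr376 (-4.44), Hs1bp3 (3.19), Srgap2 (1.77), Cxcl17 (1.08) and Hspb6 (1.39) did not pass either.

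The receptors called in different comparisons overlapped in few genes, and only receptors tested in both comparisons could be shared. Without the block no overlap could be counted because none were called. Within litters, Olfr923 was called with both doses of acetophenone and Olfr1395 with both doses of TMT. The doses of an odor share controls (those of litter 3 for acetophenone and of all 4 litters for TMT), so these overlaps were not set against independent lists. Olfr30 and Olfr376 were called with both odors at 100%, where independent lists would share 0.162 of 111 (exact hypergeometric test, 1-sided p = 0.0059, with no library in common). Olfr376 was at 0.44 ± 0.616 CPM in TMT controls, so it came among the 111 through the odor libraries in which it was high. The test also takes all 111 as equally likely to be called, so its p does not measure chance for this pair. Of the 10 receptors called with 100% acetophenone, Olfr30 and Olfr376 were the only ones among the 111 tested with both odors. The others could not be shared, so the small overlap does not show that the odors called different receptors. After the GC and length correction Olfr376 no longer passed over all genes with 100% acetophenone (log2 2.74, edgeR adjusted p = 0.0584), and Olfr30 still passed with both odors. At 1% no receptor was called with both odors, and Olfr923, the 1 receptor called with acetophenone, was not among the 107 tested with both. Across receptors, which are not independent replicates, the log2 fold changes of the doses correlated at r = 0.45 and rho = 0.37 for acetophenone (207 receptors) and r = 0.59 and rho = 0.58 for TMT (133 receptors). Unchanged groups simulated against the same controls gave r = 0.17 and r = 0.49. The simulation held no litter effect, while real libraries of a litter vary together, so the simulated values are only a rough guide. The covariance was 0.304 against a simulated 0.128 for acetophenone and 0.867 against 0.42 for TMT. With separate controls for each dose the correlation was r = 0.29 for acetophenone, from litters 1 and 2 against litters 4 and 5, and r = 0.26 on average over 6 splits of the TMT litters (0.18 to 0.38). Between odors, r was 0.14 at 100% (111 receptors) and 0.11 at 1% (107 receptors), where the simulation gave -0.01 and 0.01. The covariance between odors was 0.154 against a simulated -0.011 at 100% and 0.063 against 0.014 at 1%. At 100% its excess over the simulation (0.165) was near that between the acetophenone doses (0.176) and below that between the TMT doses (0.448), each over its own set of receptors.

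Olfr151 (M71) was listed at 0 in all 23 libraries in both columns. Whether reads on this gene could be counted is not given in the sources used here, so no limit on its level was drawn from that. Olfr160 (M72, chromosome 9, 37708964 to 37716250) had too few unique counts to pass the filter of the main fits, and fits without a filter are not given for it here. With 100% acetophenone it had 2, 44 and 20 unique counts against 3, 0 and 1 in the controls of the same litters. In the estimated counts, which were chosen after the data had been seen, it had a log2 fold change within litters of 3.32 (SE 1.09, edgeR adjusted p = 0.867) at 100% acetophenone and 1.66 (SE 0.59, edgeR adjusted p = 0.544) at 1%. Whether the reads with several alignments in that column came from Olfr160 or from Olfr151 was not tested. With 100% TMT it had 17 unique counts against 1 in controls, and 63 estimated counts against 5. The litter 4 library held 54 of the 63. Olfr160 did not enter the TMT fits, so a rise particular to acetophenone is not shown.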

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

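Tests chosen only after the result was seen were those of the 15 receptors left after scaling to receptor counts, the likeness of receptors on different chromosomes, the overlap of Olfr30 and Olfr376, the spread of the immature neuron markers, the gland and sustentacular markers, and the splits of the libraries.

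Libraries of TMT litter 1 stood apart in several measures, and as their titles carry another code series than litters 2 to 4, litter and library batch cannot be told apart. The share of counts on odorant receptors was 0.121% in the control of litter 1, against 0.0232 to 0.0362% in the other TMT controls, and 0.267% in the 1% library of litter 1, against 0.042 to 0.0708% in the other 1% libraries, with 636 receptors detected there against 240 to 275. In that 1% library Olfr1395 stood at 67.1 CPM (others 25.9 to 31.3), Olfr96 at 8.93 (others 0.101 to 0.663), Olfr350 at 8.93 (others 0.101 to 0.448), Olfr31 at 20.2 (others 0.112 to 2.42), Olfr160 at 1.32 (others 0 to 0.101) and S100a5 at 1070 (others 16.7 to 70.8). In the control of litter 1 Olfr449 stood at 10.6 CPM (others 0.169 to 0.605), Olfr31 at 9.45 (others 0 to 0.259), Olfr131 at 7.43 (others 0.169 to 1.16), Olfr350 at 2.25 (others 0 to 0.169) and Olfr160 at 0.225 (0 in the others). Olfr30 stood at 25.2 CPM in the 1% TMT library of litter 4 (others 13.8 to 15.7). A library stood apart in 15 of the 96 groups looked at. Chance gives about 1 in 20 for independent groups of normally distributed values. The groups here share libraries and receptors that vary together, and some values rest on very few reads. The count therefore does not measure how unusual these libraries are. Acetophenone groups with odor were too small to be looked at.

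Olfr160 had 221 estimated counts with 100% acetophenone, summed over litters 1 to 3, against 17 in the controls of those litters. No comparison of the report rests on that column. The unique counts were 66 and 4, and the rest were read as reads with several alignments. Of the DNA words of Olfr160, 14.7% occur in Olfr151, which had no counts in either column, and 0.315% in the next receptor, Olfr699. Whether the added reads came from Olfr160 or from Olfr151 was not tested. With litter as a block the log2 fold change of Olfr160 in the estimated counts was 3.32 with 100% acetophenone (SE 1.09, edgeR adjusted p = 0.867), so it did not pass. With 100% TMT it had 63 estimated counts against 5 in controls, 54 of the 63 in the litter 4 library, and was not tested. In the response to acetophenone and to TMT at 100%, 9 genes differed within litters by a test of the difference itself.

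The first pattern is the 36 receptors that were higher within litters with 100% acetophenone when adjusted over the list alone. Reads shared among the called receptors are argued against. The median share of 30-base words that a called receptor has in common with another called receptor was 0%. The highest was 24.4%, and 3 receptors were over 5%. With any receptor, called or not, the median was 4.39%, with 55% for Olfr749 and 37.3% for Olfr110. Sharing with receptors that were not called is therefore not excluded for each gene. The counts were read as those of uniquely aligned reads, which already leave out reads with several alignments, so word sharing is a weak test of them. A bias from GC content or length is argued against as the whole cause, since 21 of the 36 still passed after the correction, with the median log2 fold change going from 2.51 to 2.26. A rise of all receptor counts alike may account for part: with libraries scaled to their receptor counts the median log2 fold change went from 2.51 to 2.1 and 15 of the 36 still passed, so it is not the whole cause of those 15. The called receptors were more alike in protein sequence than random sets of tested receptors (12.2 against 9.14% of words of 3 amino acids, 1-sided permutation p = 0.0001, the smallest that 10000 sets can give), and so were pairs on different chromosomes or over 1 Mb apart (11.2 against 8.84%, p = 0.0001), and though 29 of the 36 lie within 1 Mb of another, nearness alone is argued against, since pairs on different chromosomes were more alike than in rotations along the genome that keep the clustering (10.9 against 8.82%, 1-sided permutation p = 0.0063). Activation of neurons whose receptors bind acetophenone is a candidate explanation that stays open, as the random sets were not matched for expression level.

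The second pattern is the pair of receptors Olfr30 and Olfr376, which rose within litters with both odors at 100%. Reads shared between these 2 genes are argued against, since 0% of the 30-base words of one gene occur in the other. A rise of all receptor counts alike is argued against for 3 of the 4 tests, which still passed with libraries scaled to their receptor counts, while Olfr30 with 100% TMT no longer passed (log2 1.14), and after the GC and length correction 3 of the 4 still passed over all genes, with Olfr376 with 100% acetophenone going from log2 3.05 (SE 0.37) to 2.74 (SE 0.39, edgeR adjusted p = 0.0584). Independent lists that meet by chance would share 2 or more of 111 receptors with an exact hypergeometric p of 0.0059, for a pair noticed first and then tested on the same data. Olfr376 came among the 111 through the TMT libraries in which it was high, and receptors differ in how readily they are called. Whether the lists met by chance is therefore not decided. Receptors that answer to both odors, or a reaction of such neurons to any strong stimulus, may each account for the pair, and neither was tested.

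The third pattern is the 304 genes other than receptors that changed within litters with 100% TMT. Without the litter 4 libraries the median ratio of log2 fold changes was 0.98, and 12 of the genes still passed. Without litters 1, 2 and 3 the ratios were 1.11, 0.92 and 0.98 with 141, 1 and 0 still past. The 304 genes were called on the same litters by a test that favours changes alike across litters. Ratios near 1 follow in part from that choice, so whether the pattern rests on the litter 4 libraries alone is not decided. A bias from GC content or length may account for much of the pattern: after the correction 49 of the 304 passed, all 304 kept their direction, and the median size of the log2 fold change went from 1.65 to 1.30 with a median SE of 0.32 before and 0.30 after; of the 255 lost calls 161 shrank by more than their SE, and 86 kept an unadjusted p under the earlier limit, which tightened as fewer genes passed. A changed makeup of cells stays open: immature neuron markers fell by unequal amounts (log2 -1.67 to 0.31, Cochran's Q against a chi-square distribution over 14 markers, which are not independent, p = 0.00351, and 0.0191 after the correction), which a baseline in other cells would also give, and 10 lay below 0 by more than 2 standard errors and 0 above (9 and 0 after the correction). Before the correction 3 of 30 gland and sustentacular markers lay below 0 by more than 2 standard errors while 17 lay above (Ugt2a1 and Ugt2a2, which share counts, are 2 of these), and 0 and 19 after the correction, so more of these cells is not excluded, and a response of the cells to TMT stays open beside it and the GC bias.

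For 100% acetophenone within litters, 11 genes were called with the real assignment and at most 0 in the other exchanges of labels within litters (1 of 4 as large), and for 1% acetophenone 1 gene against 0 (1 of 4). For 100% TMT the values were 314 genes against 0 (1 of 8), for 1% TMT 1 gene against 0 (1 of 8), and for 100% against 1% TMT 0 genes against 0 (8 of 8). These exchanges are too few for a share under 0.05. Without the block the real split called 0 genes in each comparison, so every split is as large by construction and nothing follows about chance: 10 of 10 splits for 100% acetophenone (highest other split 0), for 1% acetophenone (0) and, with the block, for the acetophenone doses (3). It was 35 of 35 for 100% TMT (highest other split 0), for 1% TMT (51) and for the TMT doses (95), and 40 of 40 drawn splits for the odor responses at 100% (5) and at 1% (0). The splits of the TMT libraries that called 51 and 95 genes were not traced to particular libraries, and what sets them apart was not tested.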

How the results depend on the processing

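Tests chosen only after the result was seen were the combinations of the replicate block with other settings, the block without each litter, the estimated counts, the correction for GC content and length, receptor shares without each litter, lists with 1 member per group of genes that share counts, and the count of lists by fry, a test that was itself fixed beforehand. Counts are genes past the threshold, then receptors among them, and the cause of a change was not tested unless given. Against the fit without a block, the replicate block gave 11 genes (10 receptors) for 100% acetophenone, 1 (1) for 1% acetophenone, 314 (10) for 100% TMT, 1 (1) for 1% TMT and 9 (1) for the odor responses at 100%, where the main counts were 0. DESeq2 gave 5 (5), 1 (1), 509 (12) and 4 (2) for these doses, 14 (3) for the acetophenone doses, 25 for the TMT doses, and 11 (1) and 1 (1) for the odor responses at 100% and 1%. All 11 acetophenone libraries with the block gave 11 (9) and 1 (1). Without a filter the acetophenone doses gave 3 genes. Receptors adjusted over the list alone without the block numbered 6 for 100% TMT and 2 for 1% TMT. Leaving out 1 replicate gave 0 to 1 genes for each TMT dose (0 to 1 receptors), 0 to 5 for the acetophenone doses and 0 to 26 (0 to 2) for the odor responses at 100%. The share of counts on receptors reversed, to ratios of 0.834 for 1% acetophenone without its replicate 3 and 0.994 for 1% TMT without its replicate 1, where the control of that litter stayed in, and over all single replicates left out these ratios ran from 0.834 to 2.11 and from 0.994 to 3.48, and that of 100% TMT from 1.69 to 3.77; without a whole litter they ran from 1.26 to 1.59, 1.73 to 2.15 and 1.61 to 2.93.

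Within litters, 100% acetophenone (main 11, 10 receptors) gave 0 (0) without the block, 119 (42) without a filter, 5 (4) with a stricter filter that tests fewer genes, 41 (23) with DESeq2, 7 (6) after the GC and length correction and 3 to 28 (1 to 19) without each litter, and 36 receptors over the list alone. For 1% acetophenone (main 1, 1 receptor) the counts were 0 (0) without the block, 60 (2) with DESeq2, 0 (0) with estimated counts, 0 to 19 (0 to 2) without each litter and 5 receptors over the list alone. For 100% TMT (main 314, 10 receptors) they were 0 (0) without the block, 559 without a filter, 547 with the stricter filter, 1490 (73) with DESeq2, 16 receptors with estimated counts, 29 (2) with only the 8 libraries compared, 71 (5) after the correction and 0 to 179 (0 to 3) without each litter. For 1% TMT (main 1, 1 receptor) they were 0 (0) without the block, 3 (2) without a filter, 2 (2) with the stricter filter, 261 (38) with DESeq2, 0 (0) with only the 8 libraries compared, 0 (0) without each litter and 2 receptors over the list alone. The TMT doses (main 0) gave 1 with robust hyperparameters, 6 without a filter, 1 with the stricter filter and 219 (11) with DESeq2. The odor responses at 100% (main 9, 1 receptor) gave 0 (0) without the block, 0 (0) with RLE scaling, 19 with robust hyperparameters, 143 (6) without a filter, 297 (14) with DESeq2, 0 (0) after the correction and 0 to 77 (0 to 2) without each litter, and at 1% (main 0) 20 with DESeq2 and 0 to 3 without each litter.

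The overlaps of called receptors, 0 without the block, were 1 between the acetophenone doses, 1 between the TMT doses and 2 between the odors at 100% with the replicate block, and 1, 2 and 2 with the block at an adjusted p of 0.1. Gene lists past the threshold numbered 7, 2, 7 and 4 for 100% and 1% acetophenone and 100% and 1% TMT. With an estimated correlation, with and without the block, there were 0 in each, with fry 0, 0, 1 and 0, and with the block and fry 0, 0, 3 and 0. With 1 member per group of genes that share counts there were 7, 2, 5 and 4, and 8, 3, 7 and 5 with the block. Among counts of genes and lists, 329 values were the same under an alternative (a count within 1.5 times the main count) and 159 were not. Among single genes and shares of counts, 1390 values kept their direction and side of the threshold, 53 came to pass, 192 no longer passed and 12 reversed (S100a5 at 100% acetophenone, at 0.00, had no direction to keep). Besides the 2 shares above, these were 10 log2 fold changes that passed under neither setting. Omp reversed at 1% acetophenone (main -0.03) to 0.09 and 0.02 without litters 4 and 5 (-0.21 without litter 3) and to 0.02 after the GC and length correction, at 100% TMT (0.13) to -0.10 without litter 4 (up to 0.29 without the others), and between the acetophenone doses (0.25) to -1.12 without the block. S100a5 reversed between the acetophenone doses (-0.80) to 0.06 without the block and between the odor responses at 1% (-0.39) to 0.20 and 0.42 without acetophenone litter 4 and TMT litter 1 (down to -1.17 without the others). Fos reversed at 1% TMT (0.24) to -0.01 without litter 3 (up to 0.62 without the others), and Egr1 between the odor responses at 1% (0.31) to -0.21 without acetophenone litter 4 (up to 0.67 without the others). Over the alternatives the edgeR or DESeq2 adjusted p ran from 1.68e-26 to 1 for Olfr745 (10 of 11 past the threshold), 1.24e-12 to 1 for Pcdh10 (10 of 11) and 3.67e-19 to 1 for Olfr923 at 1% acetophenone (8 of 11). It ran from 4.62e-12 to 0.102 for Olfr1395 at 100% TMT (9 of 13), 1.96e-18 to 0.284 at 1% TMT (7 of 13), 2.19e-17 to 0.147 for Nfil3 (10 of 13) and 6.31e-13 to 0.0964 for Tubb3 (10 of 13). Depth limits rare receptors: 3 counts correspond to 0.315 to 1.42 CPM across the 23 libraries, and to 0.394 to 0.737 CPM in the TMT controls, where Olfr376 had a mean of 0.44 CPM.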

Other observations

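Within litters and over all genes with 100% TMT, Slc12a2, the chloride cotransporter that loads olfactory neurons with chloride (log2 3.20), Ezh2, a histone methyltransferase of dividing cells (1.24), the chaperones Hsph1 (2.11) and Hspa5 (1.24), and the glutathione enzymes Gclc (0.78) and Gsta3 (2.62) rose, and Arrb2, a β-arrestin (-0.90), Calb2, a calcium-binding protein (-0.68), and Hes6 (-0.77) fell, with edgeR adjusted p from 0.0143 to 0.0491. After the GC and length correction Slc12a2 still passed (2.66, edgeR adjusted p = 0.0277) and the other 8 did not, with edgeR adjusted p from 0.0524 to 0.263. Adjusted over the list alone, 6 of 15 sustentacular markers were higher and 0 lower (5 of 14 with Ugt2a1 and Ugt2a2 as 1), 6 of 15 gland and secretory markers were higher and 2 lower, 5 of 22 transduction genes were higher and 1 lower, 3 of 11 globose basal and dividing cell markers were higher and 2 lower, 4 of 16 heat shock genes were higher and 4 lower, and 3 of 15 xenobiotic and oxidative stress genes were higher and 0 lower. After the GC and length correction the counts over the list alone were 7 of 15 sustentacular markers higher, 7 of 15 gland markers higher and 3 of 6 microvillar markers higher, with 0 lower in each. They were 2 higher and 2 lower for transduction genes, 0 and 0 for globose basal and dividing cell markers, 3 and 0 for heat shock genes and 2 and 1 for xenobiotic and oxidative stress genes.

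The remaining gene lists did not pass with either correlation in camera. Within litters with 100% acetophenone the median log2 fold changes were 0.01 for immature neuron, -0.19 for globose basal, 0.49 for horizontal basal, 0.15 for sustentacular, -0.12 for gland, -0.11 for microvillar, 0.07 for respiratory ciliated and -0.22 for red blood cell markers, -0.05 for heat shock and -0.10 for xenobiotic genes. For gland markers the mean was 0.06 and for immature neuron markers -0.09, which differ in sign from their medians. With 100% TMT the medians within litters were 0.12 for activity-dependent genes, 0.23 for mature neuron, -0.06 for globose basal, -0.26 for horizontal basal, 0.49 for microvillar, -0.19 for respiratory ciliated, -0.25 for immune, 0.03 for glia and endothelial and -0.15 for vomeronasal markers, 0.03 for heat shock, 0.50 for xenobiotic and 0.42 for sex-linked genes. Here the means of globose basal (0.35), respiratory ciliated (0.27) and immune cell markers (0.16) were positive. Vomeronasal neuron markers (camera upward) and glia and endothelial markers (camera downward) had tests opposite in sign to their medians. With 1% acetophenone, lists other than receptors, gland markers and xenobiotic genes had medians between -0.23 and 0.11 within litters, and sex-linked genes were tested only with TMT. Trace amine-associated receptors had too few tested members in each comparison for a test.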
